A study of Mus musculus with 236 samples.

How the data were processed

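Single cells were picked by micropipette from 6 dissociated mouse embryos after removal of the parietal endoderm and ectoplacental cone, per the labels' protocols. Messenger RNA was reverse transcribed from poly(A) tails in the cell lysate. For embryos I, II, III and X the cDNA was given a poly(A) tail and amplified by 20 and 12 PCR cycles, and for embryos VII and VIII it was made with SMARTScribe reverse transcriptase and amplified by 18 and 12 cycles. Amplified cDNA was tested by PCR for marker genes, cells were selected on the result, and cDNA over about 500 bp was kept by gel or beads. Selection by marker can set class sizes, the length selection can lower short transcripts, and the 2 cDNA methods differ in how many genes are listed.

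The deposited table holds values for 19104 genes in 236 cells and is titled RPKM. The deposited values were read as log2(RPKM + 1), since they reach no more than 15.8 and the smallest above 0 equals RPKM 0.01, but the log step is not given in the sources used here. RPKM scales reads by transcript length and by the reads of the cell. In every cell 284 genes are at 0. Exact zeros also occur in genes that every cell uses, so a gene is only said to be listed at 0. CASAVA 1.7, TopHat2 2.0, Cufflinks 2.2.1 and the build mm10 are named in the submitters' processing notes, without their roles. The table's header lines matched the labels in 236 of 236 cells, no 2 cells had identical values, and the highest correlation between cells was 0.994. The table gives no read counts, so the depth per cell is unknown. The mean sum of RPKM per cell was 701402 in embryo I, 672528 in II, 709908 in III, 429601 in VII, 421781 in VIII and 534022 in X, and ribosomal protein genes took 35.8%, 33.2%, 33.2%, 17.0%, 16.8% and 26.9% of it.

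Each GEO sample was 1 cell, so the embryo was the replicate. log2(RPKM + 1) was averaged over the cells of each class in each embryo, and the means were tested with limma 3.58.1 in R 4.3.3 (two-sided moderated tests with trend and robust variance), with weights n/(n + 10) for a mean of n cells. Genes with RPKM 1 or more in at least 5 cells of a fit were tested, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. Differences are on the log2(RPKM + 1) scale, which understates the change of low genes. Early classes shared 1 fit and late classes another, with the embryo as a block. The comparison of late with early EPI had a term for the cDNA method, and the stage dependence of the preMEN difference was an interaction with the embryo as a block. EXE_like cells entered the late fit and no comparison. VE_like, Other and Other_EXEM cells were left out of all tests because their classes are in 1 embryo each.

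Classes of an embryo are cells of the same animal, so the embryo pairs them. The correlation of the deviations of same-embryo means was 0.12, 0 and 0.11 for VE with EPI, 0.09, 0.03 and 0.16 for EXE, 0.10, 0.12 and 0.27 for early preMEN, 0.17, 0.18 and 0.41 for late preMEN, and 0.18, 0.28 and 0.60 for ME with EPI. It was 0.61 for DE and 0.42 for ME(EXEM) with ME. In the late embryos the cDNA method differs between X and the other embryos, so these late values mix the animal with the method.

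The groups, tests, 31 gene lists (291 genes, 279 of them in the table, 12 without a row) and the alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Genes named in the text are, per comparison, up to 6 with the largest rise and 6 with the largest fall among those past the threshold with the same direction in every embryo holding both classes, and up to 4 passing members per list by size of difference. A list member that did not pass is named with its values. Nefl in late preMEN cells was named after its values were seen, as were the other genes named where no gene passed, Wnt3 in early preMEN cells and the genes named for single cells of the small classes.

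Gene positions and transcript lengths came from GENCODE release M21 on GRCm38, the assembly that mm10 denotes: 18222 symbols matched directly and 648 by synonym, and 234 did not match. Whether reads were counted by strand is not given in the sources used here, so values of genes that overlap another gene are uncertain, among them Pou5f1, Otx2, Eomes, Nefl, Comt, Srsf4, Adnp and Bmp4.

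The tests were tried on simulated data with 200 genes shifted by known amounts. Of those shifted by 4 log2 units, 93.9% were recovered for VE, 92.4% for EXE, 97.0% for early preMEN, 50.0% for late preMEN, 84.8% for ME, 75.8% for DE, 34.8% for ME(EXEM), 90.9% for stage and 16.7% for the interaction. Of those shifted by 2 log2 units 3.0% to 41.8% were recovered, and 0 to 4 unchanged genes were called. Only genes with a mean log2 value of 2 or more were shifted. Except for stage, cells of the compared classes were drawn from the comparison class of the same embryo. The true class difference was thus the same in every embryo. For stage all late means had the same shift, so an effect of embryo X alone was not simulated. Recovery may therefore be overstated and false calls understated. A simulated list of 10 genes shifted by 1.5 had an adjusted p of 1.83e-24 by camera with the preset correlation, and no other list was called. The noise was drawn independently for each gene and the other lists were random genes. This trial therefore cannot show how often lists of correlated genes are called falsely.

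Alternatives were a pseudocount of 0.1, no filter on low values, a filter of 20 cells, equal weights, weights equal to the number of cells, the log2 of the mean RPKM, cells rescaled to a total of 1000000, no replicate block, fits of the 2 classes alone, fits without each embryo, and, for stage, no method term, all EPI cells, and poly(A)-tailed embryos alone. Added after seeing the data were fits without the tenth of each embryo's cells with the fewest genes, fits without the VE and EXE cells with titles beginning with A, and, for stage, means corrected for transcript length or centred on their median. Title series here means the first letter of the cell titles, A, Q or S, whose meaning the labels do not give. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and plots.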

Results

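Expression was measured in 236 single cells picked from 6 C57BL/6 mouse embryos, at the time when the epiblast, the tissue that forms the body, goes from a pluripotent epithelium to gastrulation. Embryos I and II were at embryonic day 5.5, embryo III at an early and embryos VII, VIII and X at a late phase of day 6.5. The submitters sorted the cells into classes: epiblast (EPI), visceral endoderm (VE, the outer layer that feeds the embryo), extraembryonic ectoderm (EXE, which forms part of the placenta), and cells labelled preMEN, ME, DE and ME(EXEM). The early embryos held 87 EPI, 21 preMEN, 8 VE and 8 EXE cells. The late embryos held 20 EPI, 11 preMEN, 46 ME, 18 DE and 7 ME(EXEM) cells, and 10 cells of 4 small classes. Classes were assigned by the submitters from the expression of these same cells, so genes that separate classes are not independent evidence that the classes exist. Cells had also been preselected by PCR for Oct4 (Pou5f1), Hand1, Gata6 or germ-layer markers, so no share of a class is given.

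Each cell listed between 3003 and 8315 genes at RPKM 1 or more. The mean was 7139 ± 552 (SD over 21 cells) in embryo I, 7069 ± 746 (29 cells) in II, 6372 ± 851 (74 cells) in III, 4137 ± 635 (14 cells) in VII, 3830 ± 484 (54 cells) in VIII and 5457 ± 858 (44 cells) in X. Embryos VII and VIII were prepared with another cDNA method than the rest. Read depth is unknown, since the table holds no counts. The number of embryos, 3 early ones from 2 labelled stages and 3 late ones, limits the precision of every comparison.

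**Figure D1:**
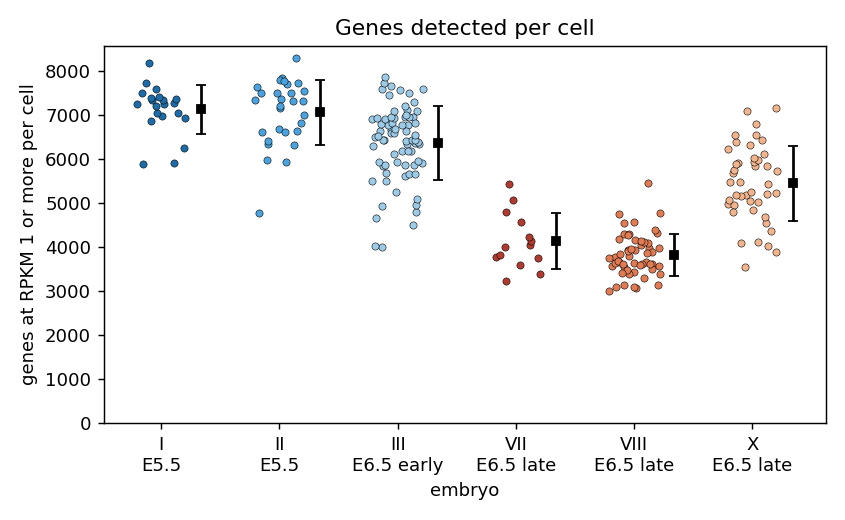
Genes listed at RPKM 1 or more (y axis, number of genes) in each of the 236 cells, by embryo (x axis), with squares and bars for the mean and SD over cells. Cells of embryos VII and VIII, made with the template-switching cDNA method, average 4137 and 3830 genes, below the 5457 of embryo X and the 6372 to 7139 of embryos I to III.

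VE cells were set against EPI cells of the same early embryos to describe the difference between the outer endoderm and the epiblast. They numbered 1, 4 and 3 in embryos I, II and III, so the VE mean of embryo I is a single cell. Apoa1, an apolipoprotein (chromosome 9, 46228580 to 46230466, GRCm38), stood at a mean log2(RPKM + 1) of 11.50 ± 0.98 in VE against 0.43 ± 0.20 in EPI (SD, n = 3 embryos), a fitted difference of 11.38 (SE 0.54, adjusted p = 3.32e-08, higher in 3 of 3 embryos). Ttr, a thyroid hormone carrier, was higher by 9.27, Apom by 9.58, the protease gene Ctsh by 8.42 and Amn, a subunit of an endocytic receptor, by 8.10. All 15 tested members of the visceral endoderm list rose, also 15 when adjusted over the list alone. Of 9 definitive endoderm genes 8 rose and 1 fell (the same numbers adjusted over the list alone), among them Gata4 (6.10), Gata6 (4.64) and Foxa2 (3.81). Gata4 and Gata6 are also on the visceral endoderm list, and Foxa2, Cer1 and Hhex on that of the anterior visceral endoderm, so these lists are not independent. Of 7 parietal endoderm genes 6 rose (7 adjusted over the list alone), including the basement membrane collagens Col4a1 (3.27) and Col4a2 (3.28), whose annotations overlap on opposite strands. Gata6 was among the genes used to preselect cells.

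Genes of the anterior visceral endoderm, the signalling part of this layer, were higher too: 7 of 8 rose (7 adjusted over the list alone, with 1 lower), among them Cer1 (5.12), Hhex (4.81), Lhx1 (3.67) and Lefty1 (3.07). Core and primed pluripotency genes were in part lower in VE. Neither list's call by camera held with an estimated correlation (adjusted p = 0.057 and 0.18). Of 10 core pluripotency genes 6 fell (7 adjusted over the list alone), led by Pou5f1 (-6.29) and Tdgf1 (-5.62), and of 14 primed epiblast genes 7 fell (8 adjusted over the list alone), such as Pou3f1 (-3.86) and Dnmt3a (-3.90). Of 11 naive pluripotency genes 2 rose and 1 fell (4 and 1 adjusted over the list alone), and that list was not called (adjusted p = 0.102). Among 15 glycolysis genes 9 fell and 1 rose (11 and 1 adjusted over the list alone): Aldoa differed by -1.49 and Gpi1 by -1.34, while the glucose transporter gene Slc2a3 was higher by 4.49. The keratin gene Krt8 was higher by 5.82, and the largest falls besides Pou5f1 were in Slc7a3 (-7.00), Ifitm2 (-6.38) and Pim2 (-6.14); Ifitm2 has close paralogs and its value is uncertain.

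limma with the embryo as a block called 736 genes higher and 909 lower in VE among 12179 tested. The majority turned to higher genes with equal weights (298 higher, 283 lower), without embryo I (556 and 526) and without embryo III (398 and 303). camera with its preset correlation called 12 lists (2 of the 31 had too few tested genes for it), and with an estimated correlation the calls of visceral endoderm (adjusted p = 0.0084), definitive endoderm (0.0091) and parietal endoderm (0.031) held. The anterior visceral endoderm and core pluripotency lists each had an adjusted p = 0.057 with an estimated correlation, primed epiblast 0.18 and glycolysis 0.21. By fry 11 of the 12 lists passed. All 4 VE cells of embryo II carried titles beginning with A while those of I and III began with S, as the EPI cells did; without them 887 genes passed, and without embryos I, II or III 1082, 438 and 701 did.

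EXE cells were compared with the same EPI cells to describe the other extraembryonic lineage. The EXE cells numbered 1, 6 and 1 in embryos I, II and III, so the EXE means of embryos I and III are single cells. Trophoblast genes marked the difference. Elf5, a trophoblast stem cell transcription factor (chromosome 2, 103411688 to 103450989), averaged 5.57 ± 0.48 in EXE (n = 3 embryos) and reached RPKM 1 in 0% of EPI cells, a difference of 5.47 (SE 0.48, adjusted p = 7.5e-06, 3 of 3 embryos). Of 14 extraembryonic ectoderm genes 13 rose (13 adjusted over the list alone), with Wnt7b at 6.23, Tfap2c at 5.5 and Bmp4, a signal to the neighbouring epiblast, at 5.14. The X-linked homeobox gene Rhox5 had the largest rise (9.63), followed by Morc4 (8.35) and the connexin genes Gjb3 (7.59) and Gjb5 (7.08). Hand1, one of the preselection genes, was higher by 6.52.

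Naive pluripotency genes, better known from the earlier blastocyst, went both ways: 5 of 11 rose and 1 fell (5 and 1 adjusted over the list alone), with Zfp42 at 6.79, Klf5 at 6.22 and Esrrb at 4.91, genes that trophoblast also uses. Of 14 primed epiblast genes 9 fell (10 adjusted over the list alone), including Otx2 (-6.68), Fgf5 (-5.26) and the DNA methyltransferase gene Dnmt3a (-4.76). Among 10 core pluripotency genes 3 fell and 1 rose (3 and 2 adjusted over the list alone): Pou5f1 (-6.81), Tdgf1 (-5.95) and Nanog (-2.56) against Dppa4 (3.75). The immediate early genes Fos (4.80) and Junb (3.97), which respond to growth signals and to handling, were higher; 2 of 9 on their list rose (4 adjusted over the list alone). Among BMP targets Id2 was higher by 6.47 and Id3 differed by -6.12, with 3 of 9 up and 1 down (4 and 1 adjusted over the list alone).

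limma called 474 genes higher and 429 lower in EXE among 12179. Of 10 lists called by camera, extraembryonic ectoderm held with an estimated correlation (adjusted p = 0.0054), while primed epiblast and naive pluripotency (both adjusted p = 0.073 with an estimated correlation), core pluripotency and the immediate early genes (both 0.2) and BMP targets (0.17) did not. By fry all 10 lists passed. Embryo II supplied 6 of the 8 EXE cells, of which 5 had titles beginning with A: 37 genes passed without embryo II, 233 without the A-titled cells and 535 without embryo I.

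Early preMEN cells were compared with the other early EPI cells, which asks how cells that the submitters set apart before gastrulation differ. Few genes passed. Eomes, a T-box factor of the primitive streak (chromosome 9, 118478212 to 118486132), averaged 4.90 ± 1.09 in preMEN and 1.83 ± 0.70 in EPI (n = 3 embryos), a difference of 2.92 (SE 0.43, adjusted p = 0.0303, 3 of 3 embryos). Nefl, a neurofilament gene (chromosome 14, 68083863 to 68089095), was higher by 3.94 (SE 0.51, adjusted p = 0.019, 3 of 3 embryos). Fgf8, a growth factor of the streak, was higher by 4.86 (SE 0.68, adjusted p = 0.0242) and in 2 of 3 embryos, since the lone preMEN cell of embryo I stood at 0.68 against 0.74 in EPI. Both Eomes and Nefl overlap another annotated gene on the opposite strand. Wnt3, which did not pass, differed by 1.54 (adjusted p = 0.301).

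These 3 genes, all higher, were the calls of limma among 12179 genes, and 493 had an unadjusted p under 0.05. The primitive streak list had 2 of 9 genes up (5 adjusted over the list alone) and was among 8 lists called by camera, with adjusted p = 0.11 with an estimated correlation, and none of the 8 held that way. None of the 8 passed by fry. No gene passed with equal weights, without embryo II, without embryo III or without the A-titled VE and EXE cells that share the fit. With no filter on low values 12 other genes passed, 2 higher and 10 lower, and none of these 3 did (adjusted p = 0.0725 for Eomes, 0.0645 for Nefl and 0.157 for Fgf8). Without the block and without embryo I 2 genes passed.

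In the late embryos the corresponding comparison of preMEN with EPI cells gave no call. Eomes stood at 6.4 ± 1.78 in preMEN against 1.34 ± 1.33 in EPI (n = 3 embryos), a difference of 4.60 (SE 0.88, adjusted p = 0.413), and was higher in 3 of 3 embryos. Nefl differed by 2.39 (adjusted p = 0.712) in 2 of 3 embryos and Fgf8 by 2.43 (adjusted p = 0.812). The epiblast genes Otx2 (-2.85) and Sox2 (-2.47) did not pass either. These genes were chosen after their values were seen. The 11 tested primitive streak genes had 0 calls (1 higher adjusted over the list alone), as had the 10 epithelial genes (1 lower adjusted over the list alone).

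limma called 0 of 10840 genes, with 673 at an unadjusted p under 0.05 and a smallest adjusted p of 0.413. camera called 5 lists, among them primitive streak and Wnt targets up and epithelial genes down, and none held: their adjusted p was 0.28, 0.16 and 0.16 with an estimated correlation. None of the 5 passed by fry. Of the 11 preMEN cells 8 came from embryo VIII, and embryo VII had 1. The preMEN cells also listed fewer genes at RPKM 1 or more than EPI cells. The means were 3761 against 4081 in embryo VII, 3479 against 3813 in VIII and 4675 against 5572 in X.

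ME cells were compared with EPI cells of the late embryos, which describes what distinguishes cells labelled ME from epiblast at gastrulation. Genes of the primitive streak and of early mesoderm were higher. Mesp1, a factor of the earliest mesoderm (chromosome 7, 79792241 to 79793788), rose from 0.36 ± 0.30 to 8.13 ± 0.74 (n = 3 embryos), a difference of 7.71 (SE 0.61, adjusted p = 3.1e-07, 3 of 3 embryos). Of 11 primitive streak genes 7 rose (10 adjusted over the list alone), with Mixl1 at 5.88, Lhx1 at 5.87, T at 4.84 and Eomes at 4.81. Of 12 nascent mesoderm genes 8 rose (12 adjusted over the list alone), including Lefty2 (5.49) and Snai1 (5.52), a repressor of epithelial genes.

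A shift from epithelial to mesenchymal genes went with it. Of 10 epithelial genes 3 fell (7 adjusted over the list alone, with 1 higher): the tight junction gene Cldn6 (-4.06), the E-cadherin gene Cdh1 (-3.14) and Epcam (-2.92). Of 9 mesenchymal genes 4 rose (6 adjusted over the list alone), such as the fibronectin gene Fn1 (4.73) and the N-cadherin gene Cdh2 (3.40). Of 8 core pluripotency genes 1 fell and 1 rose (2 and 1 adjusted over the list alone), and that list was not called (adjusted p = 0.0573): Utf1 differed by -6.70 (SE 0.83, adjusted p = 0.000311) and Tdgf1, which encodes a Nodal co-receptor, by 4.52. L1td1, on none of the lists, differed by -4.20. Of 13 primed epiblast genes 4 fell (7 adjusted over the list alone), including Pou3f1 (-3.67) and Dnmt3b (-2.65). Of 9 Wnt targets 2 rose (4 adjusted over the list alone), T and Sp5 (3.85).

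limma called 53 genes higher and 37 lower among 10840. With an estimated correlation camera's calls held for primitive streak, nascent mesoderm and epithelial genes (each adjusted p = 0.0037), mesenchymal genes and Wnt targets (each 0.0048), and not for primed epiblast (adjusted p = 0.11). Without the embryo block 47 genes passed, 1 passed with equal weights, and 12 and 26 passed without embryos VIII and X.

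**Figure D2:**
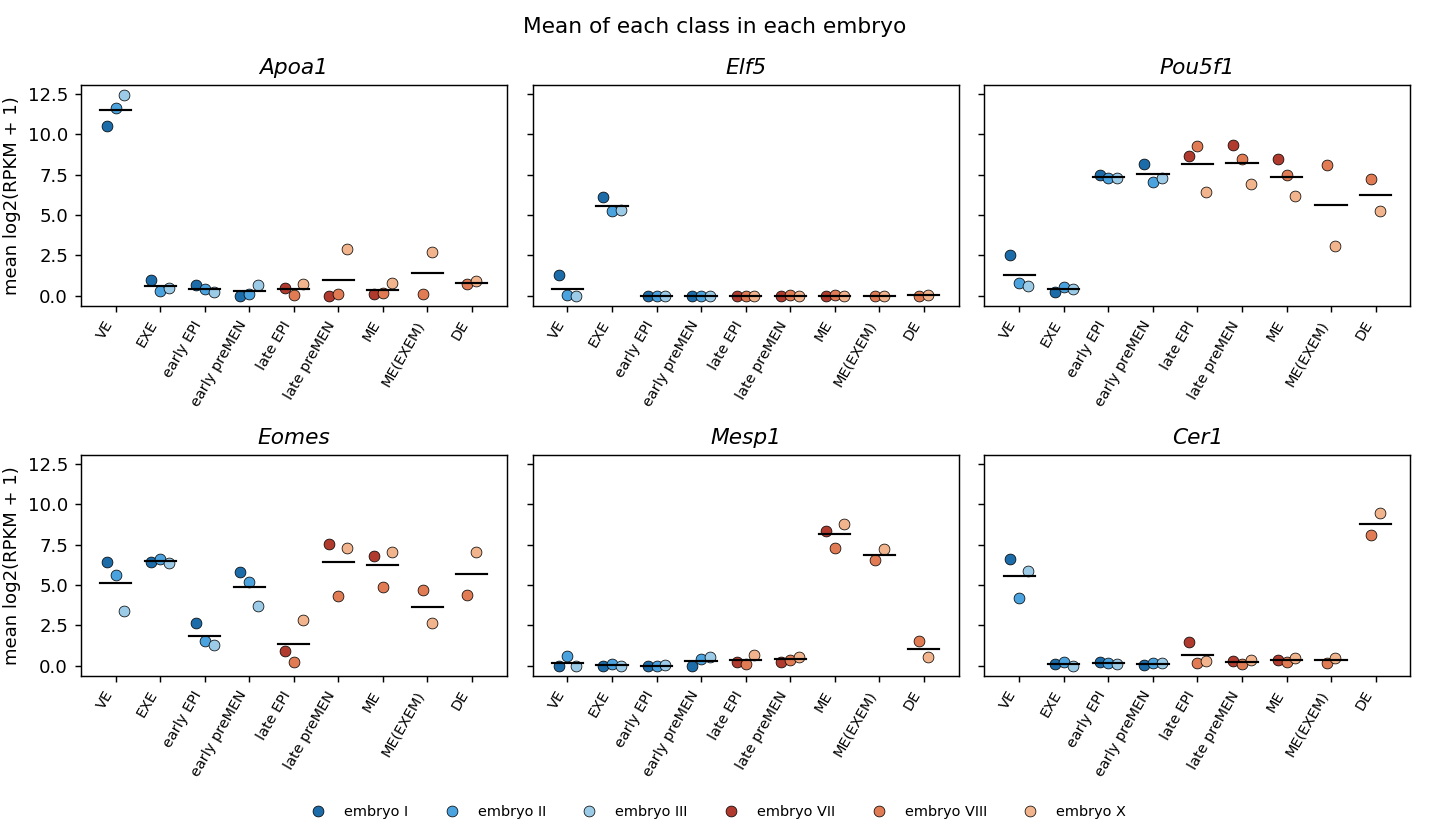
Mean log2(RPKM + 1) of selected genes (y axis) per embryo and class, for Apoa1, Elf5, Pou5f1, Eomes, Mesp1 and Cer1; each point is the mean over the cells of 1 class in 1 embryo and each line the mean over embryos. Mesp1 averages 8.13 in ME cells and 0.36 in late EPI cells, and Cer1 averages 8.79 in DE and 0.36 in ME cells.

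DE cells were compared with ME cells in embryos VIII and X, which held both, to separate the later classes from each other. Cer1, a secreted Nodal and BMP antagonist (chromosome 4, 82881751 to 82885148), was 8.79 ± 0.95 in DE (n = 2 embryos) and 0.36 ± 0.12 in ME (n = 3), a difference of 8.44 (SE 0.84, adjusted p = 1.01e-05 by limma, 2 of 2 embryos). Of 10 definitive endoderm genes 5 rose (6 adjusted over the list alone), with Foxa2 at 5.52, Hhex at 4.56 and Sox17 at 3.97. Of 7 anterior visceral endoderm genes 3 rose (6 adjusted over the list alone), namely Cer1, Foxa2 and Hhex, which are on the definitive endoderm list as well. Of 6 node and axial mesoderm genes 3 rose (4 adjusted over the list alone): Foxa2, the BMP antagonist gene Chrd (2.37) and Noto (1.38).

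Epithelial genes were higher in DE than in ME: 4 of 10 rose (8 adjusted over the list alone), namely Cldn6 (6.17), Krt18 (5.46), Cldn7 (4.06) and Krt8 (3.80). Nascent mesoderm genes were lower, with 5 of 12 down (12 adjusted over the list alone), among them Mesp1 (-7.02), Snai1 (-5.14) and Lefty2 (-4.85). The Wnt effector gene Lef1 differed by -3.68 and Mycn by -3.80.

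limma called 43 genes higher and 24 lower among 10840. The definitive endoderm, anterior visceral endoderm and nascent mesoderm lists (each adjusted p = 0.0027), the node list (0.003) and the epithelial genes (0.00082) held with an estimated correlation. Equal weights left 9 calls, and 34 and 22 were left without embryos VIII and X.

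ME(EXEM) cells were compared with ME cells, and no gene passed. Hand1, a factor of extraembryonic mesoderm and a preselection gene, averaged 7.77 ± 4.52 in ME(EXEM) (n = 2 embryos) against 1.95 ± 0.40 in ME (n = 3). The fitted difference was 4.74 (SE 1.10, adjusted p = 0.676 by limma). Its ME(EXEM) means were 4.57 in embryo VIII and 10.96 in embryo X. Bmp4 averaged 0.72 in the ME(EXEM) cells of embryo VIII and 7.92 in those of X. Its fitted difference from ME was 2.44 (adjusted p = 0.998 by limma) and turned to -0.21 with the log of mean RPKM. Both genes were chosen after their values were seen. limma called 0 of 10840 genes, with 536 at an unadjusted p under 0.05. The extraembryonic mesoderm list had 0 of 9 genes past the threshold (1 adjusted over the list alone) and was 1 of 3 lists called by camera, with adjusted p = 0.69 with an estimated correlation. Its direction was reversed without embryo X. The class had 5 cells in embryo VIII and 2 in X, and 2 genes passed without embryo VIII and 1 without X.

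EPI cells of the late embryos were compared with those of the early ones, which asks how the epiblast changes with stage. Most called genes were lower late, and the median difference over all genes tested was -0.23. Dppa4, a chromatin factor of pluripotent cells (chromosome 16, 48283733 to 48294237), averaged 0.06 ± 0.07 late and 3.86 ± 1.04 early (n = 3 embryos each), a fitted difference of -3.97 (SE 0.80, adjusted p = 0.0345, lower in 3 of 3 late embryos). Because of the term for the cDNA method the fitted stage difference rests on embryo X as the only late sample. The spread is taken from embryos I to III and from VII against VIII. This p therefore rests on no second late embryo made with the method of embryo X. With no term for the method the difference was -3.95 (adjusted p = 0.00528 by limma). Dppa5a, another gene of early pluripotency, fell by 5.46, the metallothionein gene Mt1 by 7.19, the keratin gene Krt18 by 3.45 and the FGF target Dusp4 by 3.39. The lactate dehydrogenase gene Ldha fell by 1.37. Fitted differences need not equal those of the plain means: Mt1 averaged 3.93 ± 3.08 late and 7.75 ± 0.67 early. Gm10052, with a difference of -8.08, is a processed pseudogene, and it, Mt1, Dppa5a, Ldha and Ifitm3 (-3.20) belong to families with close copies, so their values are uncertain. Among the rises were the Wnt effector gene Lef1 (3.13) and the pluripotency factor gene Sall4 (2.28). Of 10 core pluripotency genes, then, Dppa4 fell and Sall4 rose.

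Of 15 oxidative phosphorylation genes 4 fell (6 adjusted over the list alone): Atp5g1 (-3.23), Cox8a (-1.82), Ndufb8 (-2.54) and Cox4i1 (-2.27). The last pair was lower in 1 of the 3 late embryos, and the list's adjusted p was 0.00502, and 0.74 with an estimated correlation. The list lost its call with length-corrected means, with cells rescaled, with no method term and without embryo II. Acer2 differed by -6.36 and Comt by -5.28 with stage. For title series, A-titled cells of embryo II were set against S-titled cells of embryos I and III, less the same difference between EPI cells. By that measure Acer2 and Comt differed by -6.15 and -7.15 in VE and by -6.21 and -6.26 in EXE. This contrast crosses embryos and rests on few cells, such as 1 VE and 1 EXE cell in embryo I. Adnp (4.29) and Srsf4 (3.60), which rose with stage, differed by 2.94 and 3.83 between title series in VE and by 5.97 and 4.71 in EXE. In 1 of these classes the difference between title series was also over 50% of that with stage for Dppa5a (-4.16 in EXE, -1.12 in VE), Cox8a (-1.08 in EXE, -0.44 in VE) and Sall4 (1.30 in VE, 0.43 in EXE). All early EPI cells carry S titles and all late ones A or Q titles, so stage and title series cannot be told apart in EPI for any gene. Short transcripts differed more: the median fitted difference, which rests on embryo X, was -1.02 for transcripts under 750 bases and 0.07 over 5000 bases.

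limma with a term for the cDNA method called 52 genes higher and 276 lower among 11631. That fit sets the difference by embryo X against embryos I to III, because VII and VIII have their own cDNA method, and the count was 2, 0 and 6 without embryos I, II and III, 1462 and 1441 without VII and VIII, 1619 without the method term and 5 from the log of mean RPKM. With no filter on low values 287 genes were higher and 66 lower, the opposite split.

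**Figure D3:**
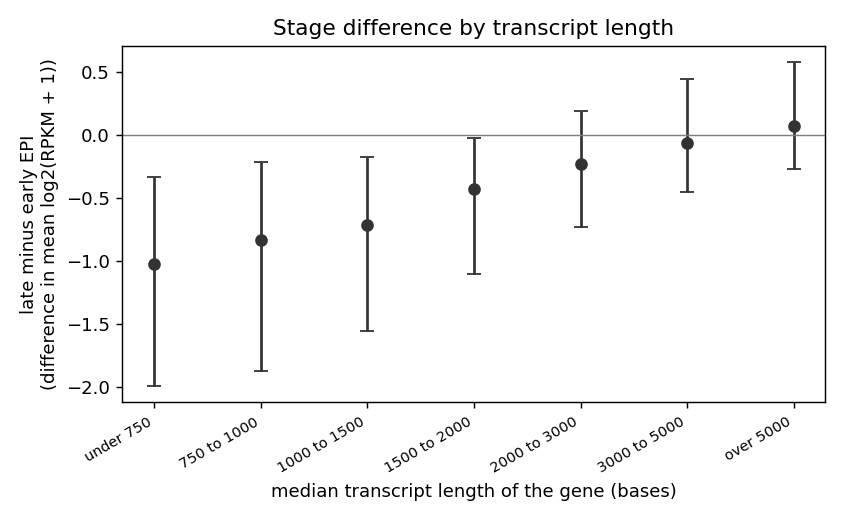
Fitted difference in log2(RPKM + 1) between late and early EPI cells (y axis) by the median transcript length of the gene in bases (x axis). Points and bars are the median and quartiles over the genes of each length range. The fit has a term for the cDNA method, so the difference rests on embryo X against embryos I to III. The median goes from -1.02 under 750 bases to 0.07 over 5000 bases.

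Whether the preMEN difference itself changed with stage was tested as an interaction. No gene passed: limma called 0 of 12014, with 568 at an unadjusted p under 0.05 and a smallest adjusted p of 0.945. For Eomes the late difference exceeded the early one by 1.72 (SE 0.93, adjusted p = 0.945), with the same sign in both stages. No list was called. In simulated data of this design 16.7% of genes shifted by 4 log2 units were recovered, and 3% of those shifted by 2, so power was low.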

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

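The 3 explanations weighed for the stage comparison and their tests, which replaced the share of lower calls after centring or length correction because these force the balance of calls, and the lists used for cells of small classes, which were cut from 5 to 3 before parietal endoderm was added, were chosen after values were seen, while the tests on Xist and on other splits were chosen before.

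Far more genes were lower than higher in late EPI cells, 276 against 52, a split that turned round with no filter on low values (66 lower, 287 higher) and with length-corrected means, which force the balance (59 and 110). A lower level of the values in late cells by a factor common to all genes is argued against as the whole cause. Such a factor would move short and long transcripts alike. A general loss that falls unequally on short and long transcripts is not covered, and depth is unknown. Among genes with a mean log2 value of 4 or more, the median difference of embryo X, which sets the fitted difference, from embryos I, II and III was -1.10, -1.03 and -1.01 for transcripts under 2000 bases and 0.23, 0.39 and 0.30 for those of 3000 bases or more, a gap of at least 1.31. Title series stays open. Between series the lower genes differed by -7.3% of their median stage difference in VE and 19.4% in EXE. Of the 276 lower genes 14, and of the 52 higher 4, differed by at least 50% in both. That contrast sets A-titled cells of embryo II against S-titled cells of I and III, less the difference between EPI cells. It rests on few cells and did not require the genes to be listed in VE or EXE. No early EPI cell is A-titled, so the contrast cannot decide for EPI cells. Transcript length stays open: of the 241 called genes with transcripts under 2000 bases 98.3% were lower, and of the 43 with 3000 bases or more 27.9%, but this trend had prompted the explanation and so does not test it. A change of the epiblast with stage stays open as well and was not tested.

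Xist, transcribed from the inactive X chromosome, was listed at RPKM 1 or more in 38.1% of the cells of embryo I and 34.5% of embryo II, where the Y-linked genes Ddx3y (means 2.78 and 3.17) and Eif2s3y (5.16 and 3.41) were also present. In embryo X, with Ddx3y at 2.94, it was 2.3%, and in embryos III, VII and VIII, with Ddx3y at 0.02 or less, it was 77%, 78.6% and 66.7%. Cells of another embryo among those of I and II are argued against, since 11.1% (2 of 18) of their Xist cells lacked both Y-linked genes, and 1 of the 32 other cells did. Reads of the antisense gene Tsix counted as Xist stay open, since mean Tsix was higher by 0.43 in embryo I and 0.22 in embryo II in cells with Xist, below the 0.5 set in advance. No biological explanation was tested.

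The counts of called genes were set against the other splits of the same 6 means, 10 splits in each case, which are too few for a share under 0.05. The real count was 1645 for VE, 903 for EXE, 3 for early preMEN, 90 for ME and 328 for stage, and the highest other split gave 0 in each, so 1 split, the real one, reached it. The other splits mix the real classes or stages, which raises the residual spread where these differ much. In some splits of the paired comparisons both means of an embryo also fall on the same side. Few calls were therefore likely in them from the start, and the 0 is no support for the real counts. For late preMEN and for the interaction the real count was 0, as in all 10 splits.

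Among the 4 EXE_like cells, 1 had 26.2% of its RPKM in ribosomal protein genes, against 17.4% in the next; this was the only gap past the limit among 16 tested in 4 classes, and chance marks about 1 in 20 groups. The test pooled cells of different embryos: this cell was the only one of embryo X, where the share averaged 26.9% over all cells, and the others came from VII and VIII, made with the other cDNA method, where it averaged 17% and 16.8%, so the cell was near the level of its own embryo.

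Cells of classes used in no comparison carried list means above the highest late EPI cell of their own embryo, shown in brackets. The 2 VE_like cells of embryo VII had a visceral endoderm mean of 7.13 (3.27) and an extraembryonic mesoderm mean of 0.31 (0.23). The 3 Other cells of embryo X had 1.04 (0.91) for extraembryonic ectoderm and 0.73 (0.06) for extraembryonic mesoderm. The Other_EXEM cell of embryo VIII had 4.34 (0.10) for extraembryonic mesoderm, 1.08 (0.32) for extraembryonic ectoderm, 1.35 (1.15) for parietal endoderm and 0.90 (0.81) for visceral endoderm. The 2 EXE_like cells of embryo VII had 5.93 (3.27) for visceral endoderm and 0.97 (0.23) for extraembryonic mesoderm. The EXE_like cell of embryo VIII had 8.64 (1.15) for parietal endoderm, 2.55 (0.81) for visceral endoderm, 0.90 (0.32) for extraembryonic ectoderm and 0.56 (0.10) for extraembryonic mesoderm. The EXE_like cell of embryo X had 4.85 (0.91) for extraembryonic ectoderm and 2.14 (0.06) for extraembryonic mesoderm.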

How the results depend on the processing

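Tests without the tenth of cells with the fewest genes, without A-titled cells and with length-corrected or centred means were chosen after seeing the data. Over all alternatives, 75 counts of calls stayed within 1.5 times the main count and 50 did not. Those that stayed include the counts of late preMEN, ME(EXEM) and the interaction that were 0 and remained 0. Most counts of stage and of early preMEN did not stay. Stage with no filter (353 genes) counts as staying, though 78 of these genes were among the main 328 and the split turned round. Named genes kept their direction and side of the threshold in 2344 cases, lost the threshold in 622 and gained it in 1; lists did so in 728 and lost it in 155. Causes were not tested except where stated.

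VE (1645 genes) gave 581 with equal weights, 887 without A-titled cells and 438 to 1082 without an embryo. EXE (903) gave 596 with no filter, 432 with equal weights, 233 without A-titled cells and 37 to 621 without an embryo. Early preMEN (3) gave 12 with no filter (2 higher and 10 lower, none of them among the main 3), 0 with equal weights, 36 with weights equal to the number of cells, 6 from the log of mean RPKM, 8 in a fit of the 2 classes, 5 without the cells with fewest genes, 0 without A-titled cells and 0 to 2 without an embryo. ME (90) gave 17 with no filter, 1 with equal weights, 220 with weights equal to the number of cells, 47 in a fit of the 2 classes and 12 to 94 without an embryo. DE (67) gave 9 and 173 with these weights and 22 to 64 without an embryo; leaving out VIII or X leaves 1 DE mean, assumed to vary like the other classes. ME(EXEM) (0) gave 2 with no filter and 0 to 2 without an embryo. The interaction (0) gave 1 with no filter.

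Stage (328) gave 514 with pseudocount 0.1, 563 with the stricter filter, 153 with equal weights, 19 higher and 120 lower (1.4e+02 in all) with weights equal to the number of cells, 5 from the log of mean RPKM, 83 with cells rescaled, 1619 with no method term, 757 with all EPI cells, 1508 with poly(A)-tailed embryos alone (of which X is the only late one), 169 with length-corrected means and 208 without the cells with fewest genes. Leaving out an embryo gave 0 to 1462; the fit without embryo X was not run, since X alone links the stages within 1 cDNA method.

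Without the replicate block ME gave 47 genes and early preMEN 2, and no other count moved by over 1.5 times. The share of lower calls moved from 55.3% to 68.9% (VE), 47.5% to 65.5% (EXE) and 41.1% to 23.3% (ME) with the log of mean RPKM, whose median shifts were -0.18, -0.23 and 0.08. In VE the share was 48.7% with equal weights, 48.6% without embryo I and 43.2% without embryo III. For stage it moved from 84.1% to 68.7% with cells rescaled (median shift 0.15), 56.2% with centring (0.27) and 34.9% with the length correction (0.22), both of which force the balance of calls and so decide nothing on its cause, 97.4% with no method term (-0.22) and 18.7% with no filter, which tests more low genes. For DE it moved from 35.8% to 11.8% with no filter, 52% with the stricter filter, 11.1% with equal weights, 22.2% without the block, 17.6% without embryo VIII and 9.1% without embryo X, and for ME to 8.3% without embryo VIII.

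Direction was reversed in 4 cases: the Wnt targets list in early preMEN with the stricter filter (adjusted p = 0.692), primed epiblast in late preMEN without embryo VIII (0.858, range 0.00313 to 0.858 without an embryo), extraembryonic mesoderm in ME(EXEM) without embryo X (0.893, range 1.76e-16 to 0.893), and Bmp4 in ME(EXEM) from the log of mean RPKM (-0.21). The oxidative phosphorylation list for stage lost its call with length-corrected means, with cells rescaled, with no method term and without embryo II. With an estimated correlation 14 of the 58 list calls held. By fry 35 of them held: 11 of 12 for VE, 10 of 10 for EXE, 7 of 11 for ME, 6 of 8 for DE and the 1 for stage. None held by fry for early preMEN, late preMEN or ME(EXEM). Depth is unknown, so no detection limit can be given.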

Other observations

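The genes named for cells of small classes were chosen after their values were seen; no explanation was tested for them.

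The 4 cells labelled EXE_like did not share 1 set of markers. The cell of embryo X carried trophoblast genes, with log2(RPKM + 1) of 5.29 for Elf5, 6.06 for Esrrb and 7.83 for Hand1, near the means of early EXE cells (5.57, 5.12 and 6.79). The cell of embryo VIII listed Elf5 and Esrrb at 0 and instead had the basement membrane genes Sparc at 11.48, Col4a1 at 10.70, Col4a2 at 9.73, Lamb1 at 9.56, Lamc1 at 9.12 and Lama1 at 8.28, with Thbd at 8.15. These are genes of parietal endoderm, a tissue that the protocol says was removed; Lamb1, Sparc and Lamc1 also averaged 1.06, 1.84 and 3.09 in EPI cells of that embryo, and the other genes less than 1. The 2 cells of embryo VII listed Elf5 at 0 and had means of 7.85 for Apoa1, 7.01 for Ttr and 5.81 for Afp, genes of visceral endoderm that stood at 10.24, 7.12 and 9.56 in the VE_like cells of the same embryo. Rhox5 was high in all 4 cells, with embryo means of 9.35, 9.49 and 10.09.

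The Other_EXEM cell had Pitx1 at 8.25, Pmp22 at 7.49, Hand1 at 7.29 and Cdx2 at 6.93, while Foxf1, another gene of extraembryonic mesoderm, was listed at 0. In the ME(EXEM) cells of embryo X the means were 10.96 for Hand1, 9.14 for Pmp22, 7.92 for Bmp4 and 7.46 for Foxf1, against 4.57, 1.62, 0.72 and 0.50 in those of embryo VIII, a difference between the 2 embryos that was not tested.

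For cells from outside the embryo, the decidua and immune cell list had 3 to 5 genes tested and 0 past limma's threshold in all 9 comparisons. These comparisons cannot show whether such cells were present, since cells found alike in both classes give no call. Adjusted over the list alone 2 were lower in VE and 1 in EXE. In VE its adjusted p was 0.109 by camera, the smallest of the 9, and 0.025 by fry, with lower values in VE than in EPI.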
